A study of Homo sapiens with 24 samples.

How the data were processed

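RNA was extracted from orthotopic HPAF-II tumours and sequenced as stranded polyA libraries, per the labels' protocols, in 24 samples. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to hg38 with STAR and quantified with RSEM; the versions of these tools are not given in the sources used here. Per the file headers, the deposited values are RSEM expected counts per gene, not normalised. Each library held 60499 gene identifiers, of which 56321 were matched to a symbol and 56769 to a GENCODE 29 gene, which gave the coordinates. Alignment to the human genome alone, as far as the notes say, leaves open how reads from mouse host tissue were treated. RSEM divides reads among near-identical genes by estimate, so values of single ribosomal protein genes, which have many pseudogenes, are less certain than the list as a whole. Gene lengths from the deposited files were used for 1 purpose, to match genes on length.

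Expected counts were rounded to whole numbers. Genes were kept by filterByExpr over the 9 groups, which left 17188. All 24 libraries entered 1 edgeR quasi-likelihood fit (edgeR 4.0.16 in R 4.3.3, limma 3.58.1) with TMM normalisation, robust dispersion estimates and 1 coefficient per group, so that the groups shared an estimate of the spread. The biological coefficient of variation was 18.3%. The 18 contrasts comprised each pair of times within a line, each pair of lines at 0 h and 6 differences between lines in their response. For genes, adjusted p is by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. All tests were two-sided unless said otherwise. Groups were taken from the sample titles.

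Gene lists, 31 of tumour pathways and 7 of host cell markers, were fixed before the data were examined. Each list was compared with the other genes by camera with a preset correlation of 0.01 and, as an alternative, with the correlation estimated from the data. Camera's p was adjusted by Benjamini-Hochberg over the lists tested in each contrast, at the same threshold. Lists with at least 5 members past the filter were tested. The lists described were chosen after the results were seen. Host markers were sparsely tested, with 9 of 20 fibroblast and 8 of 18 leukocyte markers past the filter.

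Named genes were chosen by a rule fixed before the data were examined. For 56 h against 0 h and for each line with altered MYC against WT at 0 h, these were the 8 genes with the largest rise and the 8 with the largest fall among protein-coding genes past the threshold, with a mean log2 CPM of at least 3 and no overlap between the libraries of the 2 groups. For 8 h against 0 h, MYC T58A against MYC OE and the differences in response, 4 and 4 were taken, for the last without the condition on overlap. The 10 core genes MYC, AXIN2, NKD1, RNF43, ZNRF3, NOTUM, LGR5, APCDD1, TCF7 and SP5 and the 3 members of each described list with the smallest p were added. The contrasts of 56 h with 8 h were given as counts and lists. Some genes that the rule names are not reported here.

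The fit was tested on simulated counts with 200 changed genes, 100 at each fold. For MYC T58A at 56 h it recovered 68% of 2-fold and 76% of 4-fold changes over 16865 genes, for WT at 56 h 34% and 82% over 16841 and for MYC T58A at 8 h 63% and 84% over 16862. For the difference in 56 h response it recovered 31% and 65% (MYC T58A against WT, 16846 genes) and 27% and 68% (MYC T58A against MYC OE, 16855 genes). In the order given, 5 of 149, 7 of 123, 12 of 159, 4 of 100 and 3 of 98 calls were false. Of 38 simulated lists, camera called the 1 shifted list and 0 others. The genes were simulated independently of each other, so this cannot show how often camera calls correlated lists falsely. No pair of replicates matched within sampling noise, since the chi-square per gene between replicates ran from 16.5 to 142. In MYC T58A it was 45.6 to 142 at 8 h and 16.5 to 21.6 at 56 h. The simulation gave each gene the same spread in all groups. Recovery in a group whose replicates differ more, such as MYC T58A at 8 h, was therefore not tested. The first principal component of log2 CPM held 30.2% of the variance and the next 12.2%.

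Alternatives fixed in advance were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate number as a block, a host marker score as a covariate, a fit of the compared lines alone and leaving out each library in turn. Leaving out 1 WT library leaves that group with 1, which was then assumed to vary like the other groups. A fit without the genes of the mitochondrial genome was added after the data were seen. Library totals ran from 21445530 to 37774338 expected counts, and the spread between replicates rather than depth set the precision for all but the lowest genes.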

Results

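RNA was sequenced from tumours of HPAF-II, an established human pancreatic adenocarcinoma cell line that carries a mutated RNF43 gene and depends on Wnt signalling. The cells had been grown as orthotopic xenografts in the mouse pancreas for 28 days. The mice then received ETC-159, an inhibitor of PORCN, the enzyme that attaches the lipid needed for Wnt secretion. Tumours came from 3 lines, labelled wild type (WT), MYC OE (overexpressing MYC) and MYC T58A (MYC with a phosphodegron substitution, a change known to slow its breakdown). Each line was sampled at 0 h, with vehicle, and after 8 h and 56 h of treatment. WT had 2 libraries per time, and the lines labelled MYC OE and MYC T58A had 3 per time, which made 24 libraries in 9 groups. The total of expected counts per library ran from 21445530 to 37774338. Vehicle libraries existed at 0 h alone, so time and drug could not be separated. The labels do not say whether replicates were separate animals, so p-values measured the spread between these samples. The question of the design was how the transcriptome responded to PORCN inhibition, and whether the lines with altered MYC responded differently.

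MYC itself (ENSG00000136997, chromosome 8, 127735434 to 127741434 in GRCh38, protein coding) was not higher at 0 h in the lines labelled MYC OE and MYC T58A than in WT. In vehicle it stood at 95.7 and 105.5 CPM (counts scaled to library size) in the WT libraries, at 78.4, 59.4 and 77.4 CPM in those labelled MYC OE and at 52.3, 41.4 and 25.6 CPM in those labelled MYC T58A. MYC was lower in the libraries labelled MYC T58A than in WT by a log2 fold change of -1.34 ± 0.25 (SE; adjusted p = 0.0044, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Against WT the libraries labelled MYC OE had -0.49 ± 0.25 (adjusted p = 0.38), which did not pass the test. The call in MYC T58A was lost without WT at 0 h replicate 1 (adjusted p = 0.07). Counts under MYC do not show whether transcripts of an introduced MYC were counted there, so line names below are those of the labels. At 56 h MYC fell by 1.24 ± 0.28 in WT (adjusted p = 0.0038) and by 0.78 ± 0.23 in the line labelled MYC OE (adjusted p = 0.017). In the line labelled MYC T58A the log2 fold change was -0.66 ± 0.23 (adjusted p = 0.061). The MYC OE call was lost without any of MYC OE at 0 h replicate 1, at 0 h replicate 3 or at 56 h replicate 3 (highest adjusted p = 0.079).

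**Figure D1:**
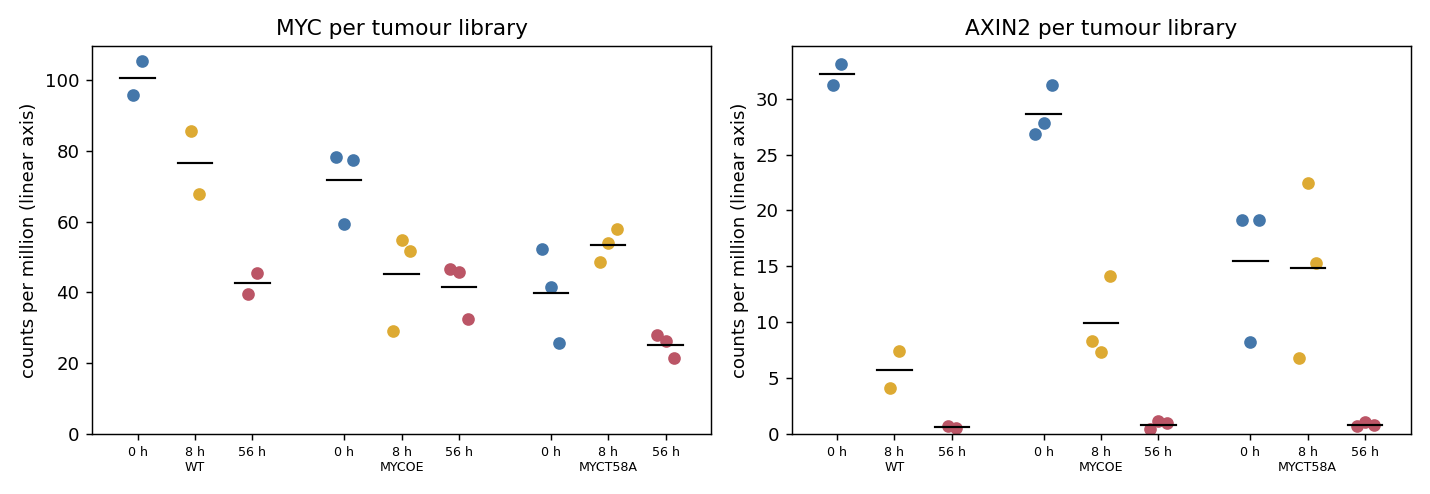
CPM of MYC (left) and AXIN2 (right) on linear axes, for each library (points) by line and hours of ETC-159, with group means (bars). AXIN2 lay between 0.417 and 1.14 CPM in the libraries labelled MYC OE at 56 h, and MYC at 0 h was highest in the WT libraries.

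Most of the tested Wnt target genes fell at 56 h in all 3 lines. AXIN2 (ENSG00000168646, chromosome 17, 65528563 to 65561647), a negative feedback regulator of the pathway, fell by 5.74 ± 0.61 on the log2 scale in WT (adjusted p = 3e-06), by 5.12 ± 0.48 in MYC OE (1.1e-06) and by 4.20 ± 0.46 in MYC T58A (1.2e-05). Its level went from 32.2 ± 1.31 CPM (SD, n = 2) to 0.6 ± 0.105 CPM in WT. NOTUM, a secreted Wnt deacylase, fell by 5.63 ± 0.50, 5.54 ± 0.38 and 6.05 ± 0.39 in the same order. NKD1, another feedback inhibitor, fell by 4.87 ± 0.53, 3.95 ± 0.41 and 3.96 ± 0.40. RNF43 and ZNRF3, which encode ubiquitin ligases that remove Wnt receptors, fell by 1.38 ± 0.26 and 1.88 ± 0.22 in WT, by 1.48 ± 0.21 and 1.58 ± 0.18 in MYC OE and by 1.35 ± 0.21 and 1.08 ± 0.17 in MYC T58A. SP5 fell by 3.02 ± 0.53, 2.83 ± 0.44 and 2.35 ± 0.44. LGR5, a receptor for R-spondin, fell in WT by 5.96 ± 1.25 (adjusted p = 0.0022; -4.43 and 0.028 without WT at 0 h replicate 1), from 311 and 58 counts in the 0 h replicates to 1 and 3 counts at 56 h, and in MYC OE fell by 3.54 ± 0.97 (0.012, and 0.063 without MYC OE at 56 h replicate 1), and had -2.27 ± 0.78 in MYC T58A (0.056). TCF7 fell by 0.97 ± 0.16 in WT and 0.67 ± 0.13 in MYC OE, with -0.31 ± 0.13 in MYC T58A (0.13). APCDD1 did not pass in any line (adjusted p = 0.59, 0.17 and 0.12) and had 22 counts or fewer in each library. Over the list of Wnt/beta-catenin targets, 26 members were tested. In WT 16 fell and 1 rose (17 and 1 adjusted over the list alone), in MYC OE 17 fell and 2 rose (17 and 2 adjusted over the list alone) and in MYC T58A 15 fell and 1 rose (19 and 3 adjusted over the list alone). The median log2 fold changes were -1.64, -1.75 and -1.22. The list passed camera against the other genes in each line, with adjusted p = 0.041, 0.025 and 0.034 with an estimated correlation. Of 558 tests of a tumour list in a contrast, 267 passed camera with the preset correlation and 10 of these, the 3 Wnt tests at 56 h among them, also passed with an estimated one. The difference in the Wnt target response between lines at 56 h had medians of 0.07 (MYC OE against WT, camera adjusted p = 0.8) and 0.22 (MYC T58A against WT, 0.062, and past the threshold without MYC T58A at 56 h replicate 1 or at 0 h replicate 1 or 3, with 0.04, 0.031 and 0.018), and 0 members passed (0 adjusted over the list alone). Between MYC T58A and MYC OE it was 0.13, with adjusted p = 0.69 with an estimated correlation, and camera's preset call was lost without MYC OE at 0 h replicate 1 (0.15) or 3 (0.14), MYC OE at 56 h replicate 1 (0.12) or 3 (0.12), MYC T58A at 0 h replicate 2 (0.15) or MYC T58A at 56 h replicate 3 (0.08).

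In WT, 3499 of 17188 genes changed at 56 h against 0 h, 1732 higher and 1767 lower. Large changes were ranked among protein-coding genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups, which leaves out AXIN2, NOTUM, SP5 and LGR5. Within that choice the largest rises were in PSCA, a prostate stem cell antigen on the surface of several epithelia (4.56 ± 0.94, adjusted p = 0.0025), FER1L6 (3.57 ± 1.04), SPRR3, a cornified envelope protein (3.44 ± 0.83), SMIM5 (3.38 ± 0.33), CST1, a cystatin (3.20 ± 0.67), FAXDC2 (3.19 ± 0.40), AKR7A3 (3.12 ± 0.41) and VSIG1 (3.10 ± 0.35). The largest falls within it were in NKD1, CDCA7, a cell-cycle regulated gene (-4.59 ± 0.32), CLDN2, a tight junction claudin (-4.51 ± 0.64), TICRR, a regulator of replication initiation (-4.08 ± 0.44), ESCO2, a cohesin acetyltransferase (-4.06 ± 0.51), DEPDC1 (-4.0 ± 0.42), BRCA1, a DNA repair gene (-3.90 ± 0.35), and ASPM, a spindle protein (-3.82 ± 0.45). Of the 24 genes named for this contrast that passed, 22 passed without each library in turn. FER1L6 was lost without any of WT at 0 h replicates 1 and 2 or WT at 56 h replicate 1 (highest adjusted p = 0.15), and SPRR3 without WT at 0 h replicate 1 (0.087). Without WT at 0 h replicate 1 or 2 the count was 2200 or 2033, and without WT at 56 h replicate 1 or 2 it was 2285 or 1996.

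In the line labelled MYC OE, 4214 genes changed at 56 h, 2125 higher and 2089 lower. PSCA rose by 3.81 ± 0.74, VSIG1 by 3.02 ± 0.29, FER1L6 by 2.95 ± 0.84, CIDEC, a lipid droplet protein, by 2.93 ± 0.45, FAXDC2 by 2.90 ± 0.33, SMPD3, a sphingomyelinase, by 2.81 ± 0.47, MUC3A, a membrane mucin, by 2.71 ± 0.55 and KLHL30 by 2.70 ± 0.23. NKD1, CLDN2 (-3.64 ± 0.50), ADAMTS14, an extracellular protease (-3.21 ± 0.31), SLC34A2, a phosphate transporter (-3.20 ± 0.47), GASK1B (-3.04 ± 0.38), LGR6, an R-spondin receptor (-2.80 ± 0.18), and DHRS2 (-2.53 ± 0.61) were among the genes that fell most within the same choice of genes. FER1L6 was lost without MYC OE at 0 h replicate 1 or 3 (highest adjusted p = 0.068). The count was 2734 without MYC OE at 56 h replicate 1.

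In the line labelled MYC T58A, 2584 genes changed at 56 h, 1251 higher and 1333 lower. CST1 rose by 3.8 ± 0.58, PSCA by 2.51 ± 0.70, VSIG1 by 2.49 ± 0.28, RAB37 by 2.43 ± 0.39, KLHL30 by 2.33 ± 0.23, SULF2, a heparan sulfatase, by 2.26 ± 0.24, KRT20, an intestinal keratin, by 2.25 ± 0.48 and CORO1A by 2.21 ± 0.23. NKD1, ADAMTS14 (-3.60 ± 0.31), GASK1B (-3.33 ± 0.38), CLDN2 (-3.28 ± 0.50), LGR6 (-3.05 ± 0.18), DHRS2 (-2.72 ± 0.61), CEMIP (-2.62 ± 0.22) and FGF3 (-2.54 ± 0.30) fell most within the same choice of genes. PSCA was lost without any of MYC T58A at 56 h replicates 1 and 2 or at 0 h replicates 2 and 3 (highest adjusted p = 0.1). The count was 1614 and 1709 without MYC T58A at 56 h replicate 1 and 3, and 1691 and 1523 without MYC T58A at 0 h replicate 1 and 3. With a host marker score in the fit it was 1584.

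Most genes of the cell-cycle lists fell at 56 h in each line. Of 51 tested genes of G2/M and mitosis, 50 fell in WT (50 adjusted over the list alone), 49 in MYC OE (50 adjusted over the list alone) and 49 in MYC T58A (50 adjusted over the list alone), and none rose. The medians were -3.02, -1.29 and -1.28. TOP2A, a DNA topoisomerase of dividing cells, fell by 3.72 ± 0.29 in WT, 1.54 ± 0.22 in MYC OE and 1.38 ± 0.21 in MYC T58A. NUSAP1, a spindle protein, fell by 3.31 ± 0.27, 1.58 ± 0.20 and 1.48 ± 0.20, and KIF15, a mitotic kinesin, by 3.78 ± 0.35, 1.5 ± 0.24 and 1.54 ± 0.24. The G2/M list had adjusted p = 0.041 in WT, 0.24 in MYC OE and 0.23 in MYC T58A with an estimated correlation. Of 50 genes of G1/S and DNA replication, 48 fell in WT (50 adjusted over the list alone), 48 in MYC OE (49 adjusted over the list alone) and 44 in MYC T58A (48 adjusted over the list alone). Their medians were -2.16, -1.27 and -1.20, with adjusted p = 0.065, 0.19 and 0.22 with an estimated correlation. LIG1, a replicative ligase, fell by 1.26 ± 0.14 in MYC OE and 1.08 ± 0.14 in MYC T58A, and MCM2, a subunit of the replicative helicase, by 2.84 ± 0.29 in WT. Nucleotide synthesis genes had medians of -0.65, -0.31 and -0.37 over 28 members, of which 14, 12 and 10 fell and 0, 1 and 1 rose (14, 12 and 13 fell and 0, 1 and 1 rose adjusted over the list alone), with adjusted p = 0.34, 0.61 and 0.54 with an estimated correlation. The lowest number of these that fell on leaving out 1 library was 9 (WT, 0 h replicate 2), 7 (MYC OE, 0 h replicate 3) and 5 (MYC T58A, 56 h replicate 1). TYMS, thymidylate synthase, fell by 3.57 ± 0.39, 1.72 ± 0.28 and 1.70 ± 0.28.

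MYC target genes moved little by comparison at 56 h. Of 60 members, 17 fell in WT (23 adjusted over the list alone), 12 fell and 1 rose in MYC OE (12 and 1 adjusted over the list alone) and 9 fell in MYC T58A (9 adjusted over the list alone). The medians were -0.32, -0.19 and -0.26, with adjusted p = 0.65, 0.92 and 0.8 with an estimated correlation. In MYC OE the median was -0.07 and -0.13 without 0 h replicate 1 and 3 and -0.13 without 56 h replicate 3, where camera's call was lost (adjusted p = 0.28, 0.11 and 0.065). MCM4 and MCM5, helicase subunits that also belong to the replication list, led it, with falls of 2.35 ± 0.28 and 1.74 ± 0.26 in WT. Of 75 genes of rRNA processing, 10 fell and 1 rose in WT (9 and 1 adjusted over the list alone), 6 fell and 1 rose in MYC OE (0 adjusted over the list alone) and 4 fell in MYC T58A (3 adjusted over the list alone), with medians of -0.19, -0.09 and -0.15 and adjusted p = 0.85, 0.96 and 0.84 with an estimated correlation. Of 77 cytosolic ribosomal protein genes, 1 fell in WT, 0 in MYC OE and 1 in MYC T58A (0 in each adjusted over the list alone), with medians of -0.29, -0.09 and -0.29 and adjusted p = 0.85, 0.96 and 0.84 with an estimated correlation. The calls of camera with the preset correlation were lost in WT without 56 h replicate 1 for ribosomal proteins (median -0.03) and rRNA processing (-0.10), and without 0 h replicate 2 for rRNA processing (-0.03). In MYC T58A the rRNA processing call was lost without 0 h replicate 1 (-0.07), 0 h replicate 2 (-0.12) or 56 h replicate 3 (-0.12). In MYC OE neither ribosomal proteins nor rRNA processing passed camera, but without 0 h replicate 2 both did (-0.19 and -0.21). The number of MYC targets that fell was as low as 8 in WT (without 56 h replicate 1), 5 in MYC OE (0 h replicate 3) and 5 in MYC T58A (0 h replicate 1). For rRNA processing it was as low as 2 (WT without 56 h replicate 1), 0 (MYC OE without 56 h replicate 1) and 2 (MYC T58A without 56 h replicate 1).

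Of 35 genes of secretory and mucin differentiation tested at 56 h, 20 rose and 1 fell in WT (21 and 2 adjusted over the list alone), 21 rose and 1 fell in MYC OE (22 and 1 adjusted over the list alone) and 14 rose and 1 fell in MYC T58A (16 and 2 adjusted over the list alone). The medians were 1.56, 1.44 and 0.70, with adjusted p = 0.24, 0.21 and 0.46 with an estimated correlation. Without WT at 0 h replicate 1, 13 rose in WT, and without MYC T58A at 0 h replicate 3, 5 rose in MYC T58A. MUC5AC, a gastric gel-forming mucin, rose by 1.99 ± 0.23 in MYC OE and by 1.57 ± 0.22 in MYC T58A, and CAPN8, a gastric calpain, rose by 1.56 ± 0.22, 1.22 ± 0.18 and 1.06 ± 0.18 in WT, MYC OE and MYC T58A. LYZ, lysozyme, fell by 1.67 ± 0.24 in WT. Genes of tight and adherens junctions had medians of 0.46, 0.46 and 0.41. Of 31 members 15, 16 and 15 rose and 1 fell in each line (16, 17 and 15 rose and 1, 1 and 2 fell adjusted over the list alone), with adjusted p = 0.1, 0.12 and 0.23 with an estimated correlation. CGN, cingulin, rose by 0.98 ± 0.14, 0.94 ± 0.12 and 0.84 ± 0.12, and F11R, a junctional adhesion molecule, by 0.99 ± 0.14, 0.78 ± 0.11 and 0.59 ± 0.11.

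**Figure D2:**
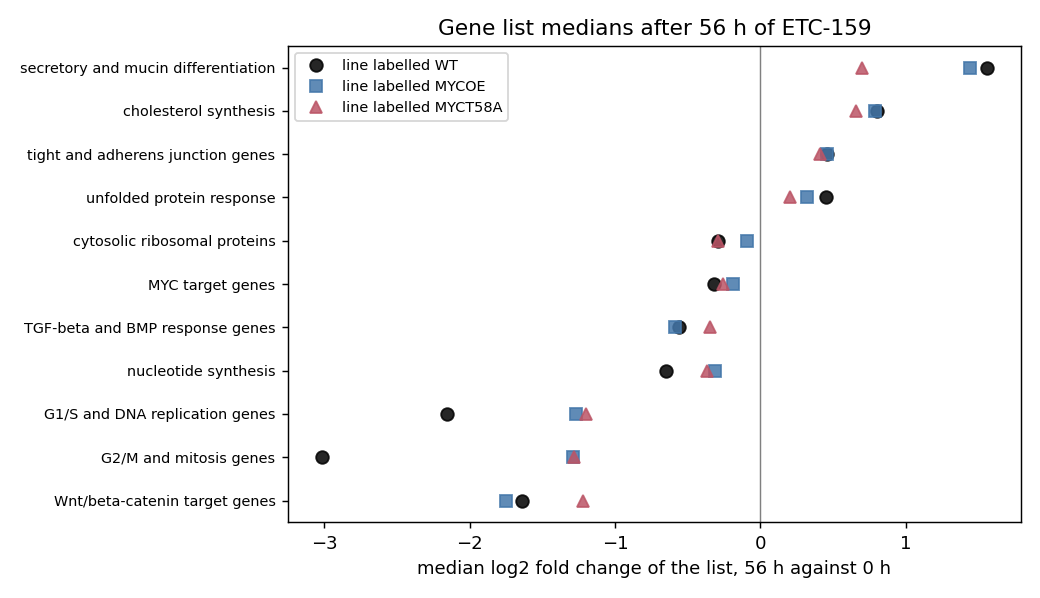
Median log2 fold change of 11 gene lists at 56 h against 0 h (horizontal axis), with 1 symbol per line. The G2/M list lay at -3.02 in WT, -1.29 in MYC OE and -1.28 in MYC T58A, and the Wnt target list at -1.64, -1.75 and -1.22.

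The genes called at 56 h overlapped between lines, whose libraries were all different. MYC OE and WT shared 1377 higher and 1285 lower genes, where independent lists would share 214.1 and 214.8. MYC T58A and WT shared 859 and 896 (126.1 and 137 for independent lists), and MYC T58A and MYC OE shared 1036 and 1034 (154.7 and 162). The log10 of the adjusted p of Fisher's exact test, one-sided, was -632.8 or lower for each. The adjustment was over the overlaps tested at 8 h and 56 h, with genes treated as independent, which they are not. Across lines 1 gene was called in opposite directions, between MYC T58A and WT. Across the 17188 genes, which are not independent replicates, the log2 fold changes correlated at Pearson's r of 0.69 (MYC OE with WT), 0.6 (MYC T58A with WT) and 0.65 (MYC T58A with MYC OE).

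In WT at 8 h AXIN2 fell by 2.48 ± 0.48 (adjusted p = 0.031), NKD1 by 2.21 ± 0.44 (0.036) and ETS2 by 1.17 ± 0.22 (0.025), and in MYC OE ZNRF3 fell by 0.83 ± 0.17 (0.024) and SP5 by 1.76 ± 0.41 (0.04). AXIN2 had -1.53 ± 0.38 in MYC OE (0.055) and -0.06 ± 0.37 in MYC T58A (0.98). The MYC T58A libraries did not move together. AXIN2 stood at 19.1, 8.20 and 19.2 CPM in replicates 1, 2 and 3 at 0 h and at 6.76, 22.4 and 15.3 CPM at 8 h, and the mean log2 CPM of the Wnt targets was 4.39, 3.97 and 4.6 at 0 h and 3.92, 4.56 and 4.28 at 8 h. In the other lines that mean was 4.51 to 4.65 at 0 h and 3.76 to 4.13 at 8 h, so both replicate 2 libraries of MYC T58A went against their times. MYC T58A replicate 1 at 0 h (4.39) and replicate 3 at 8 h (4.28) lay between those ranges. Of the 26 Wnt targets, 3 fell in WT (8 adjusted over the list alone), 2 in MYC OE (10 fell and 1 rose adjusted over the list alone) and 0 in MYC T58A (0 adjusted over the list alone). The medians were -0.72, -0.66 and -0.03, with adjusted p = 0.48, 0.12 and 0.97 with an estimated correlation. The response of MYC T58A differed by 0.56 from WT and 0.40 from MYC OE, with adjusted p = 0.15 and 0.088 with an estimated correlation, and on leaving out 1 library 0 Wnt targets passed in WT and 0 to 4 in MYC OE. These values include the replicate 2 libraries, and no fit left out both of them. Without MYC T58A at 0 h replicate 2 or at 8 h replicate 2 the MYC T58A median was -0.20 or -0.30, the difference from WT 0.60 or 0.44 and that from MYC OE 0.36 or 0.37. Without replicate 1 or 3 at either time the median turned, to 0.02 to 0.09. The difference was then 0.57 to 0.83 from WT and 0.39 to 0.66 from MYC OE. Outside the pathway, GAD1, glutamate decarboxylase, fell by 1.74 ± 0.24 in WT and 0.95 ± 0.19 in MYC OE. In WT, SCML1 (-1.73 ± 0.31) and ARID5B (-1.66 ± 0.33) also fell, and MT-ND6 (1.53 ± 0.25), HR (1.39 ± 0.25), PHLDA2 (1.26 ± 0.26) and RNF223 (1.25 ± 0.27) rose. In MYC OE, BMP2 (1.59 ± 0.36), ECM1 (1.46 ± 0.31), the immediate-early gene FOS (1.45 ± 0.28) and PTPRH (1.39 ± 0.27) rose, and INHBB (-1.16 ± 0.28), SLC26A9 (-1.04 ± 0.24) and CEP85L (-0.99 ± 0.24) fell. The share of counts from the mitochondrial genome was 11.25 to 14.32% in the WT libraries at 8 h and 5 to 6.78% at 0 h.

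In all, 67 genes changed at 8 h in WT (30 higher, 37 lower), 184 in MYC OE (145 higher, 39 lower) and 0 in MYC T58A, by edgeR's quasi-likelihood test. DESeq2 called 669, 729 and 2. The 0 of MYC T58A includes the replicate 2 libraries that went against their times on Wnt targets, and the split of the same 6 libraries that exchanges these gave 597 genes. At an unadjusted p under 0.05, 3267, 2834 and 1162 genes passed, with 859 expected by chance. The WT count was 0 without WT at 8 h replicate 1 or 2 or WT at 0 h replicate 1 and 7 without WT at 0 h replicate 2. The MYC OE count was 0 without MYC OE at 0 h replicate 1 or 3, 7 and 5 without MYC OE at 8 h replicate 1 and 3, and 684 and 496 without MYC OE at 0 h and at 8 h replicate 2. No gene named at 8 h passed without each library in turn. MYC targets had 0, 1 and 0 members higher over all genes and none lower (in MYC OE 2 higher and 21 lower adjusted over the list alone, and 16 lower over all genes without MYC OE at 0 h replicate 2). Their medians were 0.27 in WT, -0.34 in MYC OE and -0.06 in MYC T58A, with adjusted p = 0.66, 0.32 and 0.87 with an estimated correlation. The secretory list had medians of 0.57, 0.77 and 0.44, with 0 members past the threshold in each line (0 adjusted over the list alone; 3 over all genes in MYC OE without 0 h replicate 2) and adjusted p = 0.66, 0.29 and 0.69 with an estimated correlation. The G2/M list had medians of 0.16, -0.21 and -0.02, with 0 members past the threshold (0 adjusted over the list alone) and adjusted p = 0.77, 0.68 and 0.97 with an estimated correlation. Camera's calls with the preset correlation at 8 h were lost for MYC targets in WT without 0 h replicate 1 (0.14) and in MYC T58A without 0 h replicate 2 or 8 h replicate 3 (-0.04 each), where 0 h replicate 1 or 8 h replicate 2 turned the sign (up to 0.03). The secretory call in MYC T58A was lost without 0 h replicate 2 (0.32) or 8 h replicate 2 (0.09). The G2/M call was lost in WT without 8 h replicate 2 (0.10) and turned without 0 h replicate 1 (-0.26), and was lost in MYC OE without 8 h replicate 1 (-0.05) or 0 h replicate 3 (-0.06). In MYC T58A it was gained without 8 h replicate 1 (-0.14) or 0 h replicate 3 (-0.15).

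Between 8 h and 56 h, 2355 genes changed in WT (1059 higher, 1296 lower), 1881 in MYC OE (817 and 1064) and 1722 in MYC T58A (711 and 1011). The Wnt target medians over this interval were -0.72, -0.87 and -1.22, with adjusted p = 0.22, 0.049 and 0.014 with an estimated correlation. Of its 26 members 8, 9 and 14 fell and 2, 1 and 1 rose (9, 13 and 15 fell and 2, 1 and 2 rose adjusted over the list alone). The MYC T58A values over this interval include 8 h replicate 2, which went against its time on these genes. The G2/M medians were -3.15, -1.09 and -1.25, with 50, 44 and 44 of 51 genes lower (50, 48 and 49 adjusted over the list alone) and adjusted p = 0.016, 0.22 and 0.15 with an estimated correlation. MYC targets had medians of -0.67, 0.16 and -0.18, with 31, 3 and 5 of 60 genes lower and 0, 2 and 0 higher (44, 2 and 5 lower and 0, 1 and 0 higher adjusted over the list alone) and adjusted p = 0.34, 0.77 and 0.94 with an estimated correlation. Without WT at 56 h replicate 1, 8 MYC targets fell in WT, without WT at 8 h replicate 1, 5 Wnt targets did, and without MYC OE at 8 h replicate 2, 23 G2/M genes fell in MYC OE. The WT count was 915 and 1314 without WT at 8 h replicate 1 and 2 and 873 without WT at 56 h replicate 1. The MYC OE count was 897 without MYC OE at 56 h replicate 1 and 1130 without MYC OE at 8 h replicate 3. The MYC T58A count was 1032, 1087 and 967 without MYC T58A at 56 h replicate 1, 2 and 3, and 1086 without MYC T58A at 8 h replicate 1. Without MYC T58A at 8 h replicate 2 it was 2233. Camera's preset call for MYC targets was lost in MYC OE without 8 h replicate 1 (0.08), 56 h replicate 1 (0.12) or 56 h replicate 2 (0.11), and in MYC T58A without 8 h replicate 1 (-0.09).

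Before treatment, lists of growth genes had higher medians in the libraries labelled MYC T58A than in WT. With every library in the fit all 77 cytosolic ribosomal protein genes tested were higher (77 adjusted over the list alone), with a median log2 fold change of 0.96, and RPL14 (1.04 ± 0.15), RPL22 (0.96 ± 0.15) and RPS18 (1.08 ± 0.17) had the smallest p. Of 60 MYC targets 41 were higher (54 adjusted over the list alone; median 0.66), among them SORD (1.06 ± 0.17), the cell-cycle kinase CDK4 (0.90 ± 0.17) and EXOSC5 of the RNA exosome (0.93 ± 0.18). Of 75 rRNA processing genes 42 were higher (64 adjusted over the list alone; median 0.57), including WDR3 (0.90 ± 0.14) and RPF2 (0.95 ± 0.16). Of 28 nucleotide synthesis genes 15 were higher (20 adjusted over the list alone; median 0.61), including IMPDH2 (1.0 ± 0.17) and PAICS (1.0 ± 0.19). Translation factors (18 of 39 higher, 30 adjusted over the list alone; median 0.50), mitochondrial ribosomal proteins (20 of 72, 48 adjusted over the list alone; 0.42) and subunits of RNA polymerases I and III (10 of 33, 17 adjusted over the list alone; 0.41) had fewer members past the threshold. No member of these lists was lower. Without WT at 0 h replicate 1, 11 genes differed in all and 0 members of each of these lists passed, while the medians of the ribosomal protein, MYC target and rRNA processing lists were 0.91, 0.53 and 0.47. Without MYC T58A at 0 h replicate 1 the members past the threshold numbered 61 of the ribosomal proteins, 12 of the MYC targets, 14 of rRNA processing, 5 of nucleotide synthesis, 13 of the translation factors, 0 of the mitochondrial ribosomal proteins and 3 of the polymerase subunits. The share of counts from the mitochondrial genome averaged 9.66% in MYC T58A (7.52 to 12.16%) and 5.89% in WT (5 to 6.78%), and host leukocyte markers had a median of -0.60 in the same comparison (2 of 8 lower, adjusted p = 0.14 with an estimated correlation). G1/S genes had a median of 0.36 with 2 of 50 higher (0 adjusted over the list alone; 17 over all genes without WT at 0 h replicate 2) and adjusted p = 0.57 with an estimated correlation. With an estimated correlation the adjusted p was 0.14 for the ribosomal protein, MYC target, rRNA processing, translation factor and polymerase lists, 0.18 for nucleotide synthesis and 0.25 for mitochondrial ribosomal proteins. Interferon response genes had a median of -0.25 with 7 of 40 lower (7 adjusted over the list alone; 0 over all genes without WT at 0 h replicate 1 and 1 or 2 without any other library), IRF1 among them (-0.67 ± 0.16), and adjusted p = 0.6 with an estimated correlation. Wnt targets had a median of -0.24 with 2 lower (3 adjusted over the list alone), TCF7 (-0.74 ± 0.15) and ETS2 (-0.77 ± 0.19), and adjusted p = 0.42 with an estimated correlation. TCF7 was lost without WT at 0 h replicate 1 (adjusted p = 0.1). The G1/S median was 0.02 without WT at 0 h replicate 1, the interferon median -0.10 without WT at 0 h replicate 2, and the Wnt target median -0.17 and -0.29 without MYC T58A at 0 h replicate 2 and WT at 0 h replicate 2, and in each of these camera's preset call was lost.

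Over all genes, 1313 differed between the libraries labelled MYC T58A and WT at 0 h, 796 higher and 517 lower. Within the choice of genes used for the 56 h rankings, the largest differences upward were in SERPINF1, an angiogenesis inhibitor (2.51 ± 0.36), C6orf15 (2.35 ± 0.50), the transcription factor SOHLH2 (2.13 ± 0.22), SLC43A1, an amino acid transporter (1.93 ± 0.19), LOXL1 (1.72 ± 0.27), CTHRC1 (1.68 ± 0.26), FABP5 (1.64 ± 0.38) and CGREF1 (1.45 ± 0.22). Downward they were in PLEKHS1 (-2.20 ± 0.33), CYP4B1 (-1.97 ± 0.53), DMBT1 (-1.90 ± 0.56), GBP4, an interferon-induced GTPase (-1.85 ± 0.48), SLC28A3 (-1.77 ± 0.46), EPHA4 (-1.65 ± 0.43), PTGS2, cyclooxygenase 2 (-1.58 ± 0.40), and MGAM2 (-1.58 ± 0.38). Without WT at 0 h replicate 1 it was 11, and without MYC T58A at 0 h replicate 1 it was 478. Of the 18 named genes that passed, SOHLH2, SLC43A1 and PLEKHS1 passed without each library in turn. Each of the other 15 was lost without WT at 0 h replicate 1, and 9 of them also without another library (highest adjusted p = 0.39). With a host marker score in the fit the count was 769.

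The line labelled MYC OE differed from WT at 0 h in 3 genes, 2 higher and 1 lower, with 2471 at an unadjusted p under 0.05 and 207 by DESeq2. SOHLH2 (1.54 ± 0.22) and SLC43A1 (1.09 ± 0.18) were higher there as well, and PCDHGA4 (-1.77 ± 0.29), named after its values were seen, was lower. Both were lost without WT at 0 h replicate 1 (highest adjusted p = 0.88), and SLC43A1 also without WT at 0 h replicate 2 or MYC OE at 0 h replicate 1. The count was 0 without WT at 0 h replicate 1, 1 without WT at 0 h replicate 2 or MYC OE at 0 h replicate 1, and 482 without MYC OE at 0 h replicate 2. No ribosomal protein or MYC target passed over all genes, while adjusted over the list alone 72 of 77 and 46 of 60 were higher. Their medians were 0.54 and 0.51, with adjusted p = 0.25 for both with an estimated correlation. Between MYC T58A and MYC OE, 3 genes differed at 0 h, all lower in MYC T58A, with 1340 at an unadjusted p under 0.05 and 77 by DESeq2. CCDC40 (-1.43 ± 0.24, adjusted p = 0.049) was the one above the expression minimum, and was lost without any 1 of the 6 libraries. RAB36 (-1.57 ± 0.27) and LYPD6 (-1.60 ± 0.25) were the other 2, named after their values were seen. The count was 0 without any 1 of the MYC T58A libraries at 0 h or of MYC OE at 0 h replicates 2 and 3. The ribosomal protein list had a median of 0.43 between these lines, with 0 of 77 past the threshold (55 adjusted over the list alone) and adjusted p = 0.57 with an estimated correlation.

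Whether the lines responded differently was tested as the difference between their changes. At 56 h the G2/M list differed by medians of 1.69 (MYC OE against WT) and 1.67 (MYC T58A against WT). Over all genes 1 and 9 of its 51 members passed (47 and 47 adjusted over the list alone), with adjusted p = 0.021 and 0.12 with an estimated correlation. Without WT at 56 h replicate 1 the 9 were 0, and without WT at 0 h replicate 1 the numbers were 33 and 37. The G1/S list differed by 0.74 and 0.88, with 0 and 2 of 50 members past the threshold (20 and 26 adjusted over the list alone; 12 and 16 over all genes without WT at 0 h replicate 1) and adjusted p = 0.3 and 0.65 with an estimated correlation. TOP2A differed by 2.18 ± 0.34 in MYC OE (adjusted p = 0.028) and 2.34 ± 0.34 in MYC T58A (0.01). CDCA7 differed by 2.53 ± 0.38 (0.023) and 3.01 ± 0.38 (0.0014). In MYC T58A, DEPDC1 (2.72 ± 0.49, 0.039), KIF14 (2.46 ± 0.49) and KIF18B (2.38 ± 0.47), the last 2 being mitotic kinesins, also fell less. JUND, an AP-1 transcription factor, had a difference of -1.52 ± 0.30. The adjusted p of KIF14, KIF18B and JUND was 0.05 after rounding. Mean log2 CPM of the G2/M list was 2.51 and 3.02 in the WT libraries at 56 h and between 4.31 and 4.71 in the other lines. At 0 h it was 5.08 in WT replicate 1 and 5.98 in WT replicate 2.

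**Figure D3:**
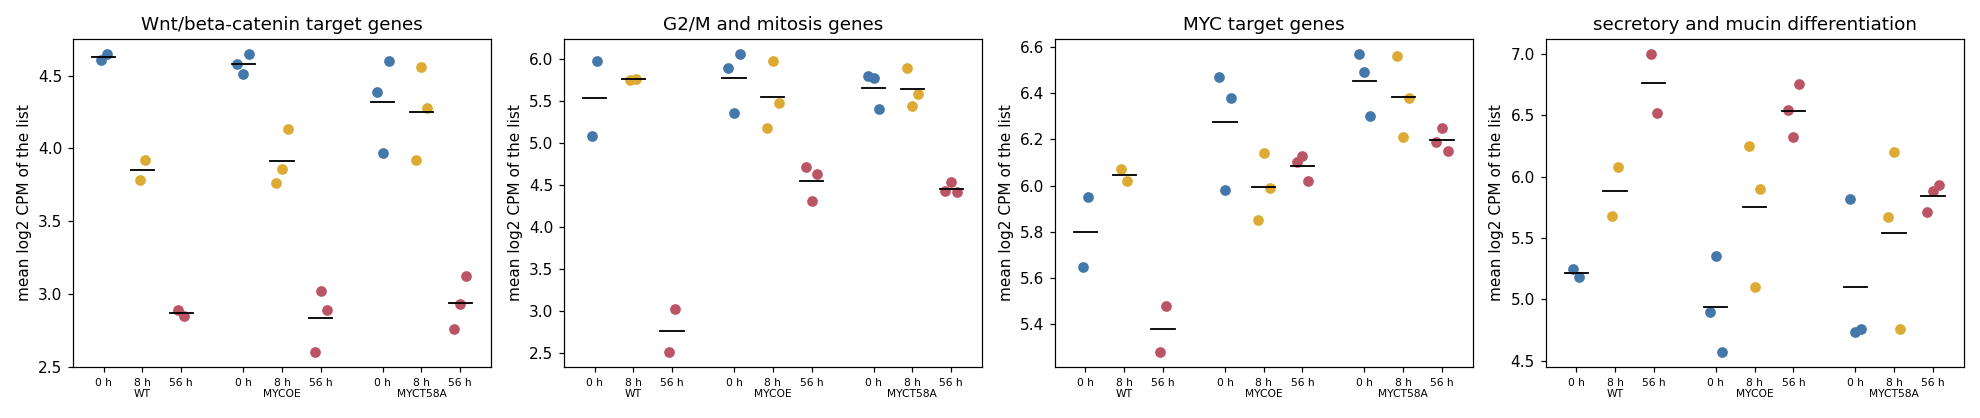
Mean log2 CPM of the tested genes of 4 lists in each library (points) by line and hours of ETC-159, with group means (bars). In the G2/M panel the WT libraries at 56 h lie at 2.51 and 3.02, below all others.

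In counts, 2 genes differed in their 56 h response between MYC OE and WT, both higher, and 25 between MYC T58A and WT, 24 higher and 1 lower. At an unadjusted p under 0.05, 645 and 1655 genes passed, with 859 expected by chance. DESeq2 called 86 and 159. Single libraries moved these counts. Without WT at 56 h replicate 1 or 2 both counts were 0, and without WT at 0 h replicate 1 they were 97 and 125. Without WT at 0 h replicate 2 they were 0 and 1. The MYC OE count was 0 without MYC OE at 0 h replicate 1 or 2 or at 56 h replicate 3, 1 without MYC OE at 56 h replicate 1, 8 without MYC OE at 56 h replicate 2 and 27 without MYC OE at 0 h replicate 3. The MYC T58A count was 5, 3 and 3 without MYC T58A at 56 h replicate 1, 2 and 3, and 4, 4 and 3 without MYC T58A at 0 h replicate 1, 2 and 3. No named gene of these comparisons passed in every such fit. Between MYC T58A and MYC OE, 0 genes differed in their 56 h response by edgeR, and 1 by DESeq2. At an unadjusted p under 0.05 there were 704, with 859 expected by chance. EdgeR called 1 without MYC OE at 56 h replicate 2 or MYC T58A at 56 h replicate 1. The G2/M list differed there by a median of 0.01 (camera adjusted p = 0.74), but by 0.19 without MYC OE at 0 h replicate 2, where it passed (0.0013), and by -0.12 without MYC OE at 0 h replicate 3 (0.054). The secretory list had median differences in MYC T58A of -0.79 against WT and -0.60 against MYC OE, 0 members past the threshold (0 adjusted over the list alone) and adjusted p = 0.65 and 0.69 with an estimated correlation. At 8 h 0 genes differed in response by edgeR between any of the lines. DESeq2 called 47 (MYC OE against WT), 2 (MYC T58A against WT) and 1 (MYC T58A against MYC OE). In that order 2585, 853 and 518 genes had an unadjusted p under 0.05, with 859 expected by chance for each. The counts of MYC T58A include the replicate 2 libraries that went against their times. Without MYC OE at 8 h replicate 3, 1 gene differed between MYC OE and WT.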

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

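All tests of explanations in this part were chosen after the result was seen, except the test of short transcripts. What drew attention to each result was a difference between lines in the response to treatment, by a test of the difference itself, and in addition the MYC counts and the ribosomal protein genes at 0 h.

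At 56 h the response of the G2/M list in the lines labelled MYC OE and MYC T58A differed from that in WT, where the fall was larger, by medians of 1.69 and 1.67, with adjusted p = 0.021 and 0.12 with an estimated correlation and 1 and 9 of 51 members past the threshold, and that of the G1/S list by 0.74 and 0.88, with 0.3 and 0.65 and 0 and 2 of 50 members. The G2/M difference of MYC T58A was at least 1.14 without any 1 WT library, which argues against 1 WT library as the whole source. It was 1.63 with the host marker score as a covariate. That score cannot decide on host tissue, since it rests on human genes. Some of these, such as LYZ and FN1, also stand in lists of tumour genes used here. The calls of single genes were less stable, since the 2 and 25 genes became 0 and 3 with that covariate, and 0 without WT at 56 h replicate 1 or 2. A lasting effect of altered MYC on proliferation stays open as a hypothesis. Clonal differences between the lines, which may have arisen when they were made, were not tested.

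MYC counts were lower at 0 h in the line labelled MYC T58A than in WT (-1.34, adjusted p = 0.0044 by edgeR, and 0.07 without WT at 0 h replicate 1), while the -0.49 of MYC OE did not pass (0.38). An exchange of the WT and MYC T58A labels would put MYC target genes lower in MYC T58A, whereas their median was 0.66 higher, with adjusted p = 0.14 with an estimated correlation. In the line labelled MYC OE, MYC fell at 56 h with a log2 fold change of -0.78, as it would if the counts came mostly from the endogenous gene. This call was lost without MYC OE at 0 h replicate 1 or 3 or at 56 h replicate 3. The fall would also occur if part of the counts were endogenous, or if introduced transcripts fell, so it does not decide. In MYC T58A, the line whose counts were lower by the test, MYC also moved downward at 56 h but did not pass. That does not show a difference between the lines. Transcripts of the introduced MYC, which may differ in sequence or lack the endogenous ends, were not analysed here. Lower endogenous MYC where more MYC protein is made is a biological explanation that was not tested.

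Ribosomal protein genes were higher in MYC T58A than in WT at 0 h, with a median of 0.96. The 82 genes matched to them on length and expression, 408 to 1111 bases long, had a median of 0.11 (95% bootstrap interval 0.07 to 0.17), with 9 higher and 3 lower. They share the same libraries and are not independent replicates. Across genes, Spearman's rho of the log2 fold change with length was -0.15, so shorter genes tended to be higher. The matched genes argue against a bias toward short transcripts as the whole source, but not against a part. The median was 0.91 and 0.97 without WT at 0 h replicate 1 and 2, which argues against 1 WT library as the source of the median, although 0 and 56 of the 77 genes then passed. Higher MYC activity is a candidate explanation that the line labels give, and with an estimated correlation the list had adjusted p = 0.14. Differences in tumour handling stay open, with a mean mitochondrial genome share of 9.66% against 5.89% and a median of -0.60 for host leukocyte markers in the same comparison.

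Among single genes, the difference in 56 h response between MYC OE and WT was 2.53 for CDCA7 and 2.18 for TOP2A. Between MYC T58A and WT it was 3.01 for CDCA7, 2.72 for DEPDC1, 2.46 for KIF14, 2.38 for KIF18B and -1.52 for JUND. None of these passed in every fit without 1 library. CDCA7 in MYC T58A was lost without WT at 56 h replicate 1 or 2 (highest adjusted p = 0.064), and JUND without any of the 10 libraries.

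At 8 h the MYC target response differed by a median of -0.63 (MYC OE against WT), -0.35 (MYC T58A against WT) and 0.25 (MYC T58A against MYC OE), with adjusted p = 0.5, 0.51 and 0.71 with an estimated correlation. The Wnt target response at 8 h differed by 0.56 (MYC T58A against WT) and 0.40 (MYC T58A against MYC OE), with adjusted p = 0.15 and 0.088 with an estimated correlation. On leaving out 1 library these differences ran from 0.44 to 0.83 and from 0.30 to 0.66. In MYC T58A the replicate 2 libraries went against their times on these genes, and both enter these differences. No fit left out both, so the ranges cannot show how large the differences are without them. The mean log2 CPM of the Wnt targets was 0.59 higher at 8 h than at 0 h in replicate 2, against -0.47 and -0.32 for replicates 1 and 3. The replicate numbers did not pair the samples. For glycolysis and hypoxia genes at 8 h the difference was 1.21 (MYC OE against WT) and 0.41 (MYC T58A against WT, -0.03 without MYC T58A at 8 h replicate 3, and 0.40, 0.35 and 0.15 with the preset call lost without WT at 8 h replicate 1, MYC T58A at 0 h replicate 1 and WT at 0 h replicate 1), with adjusted p = 0.5 and 0.76 with an estimated correlation. At 56 h MYC targets differed by 0.20 and 0.15 in MYC OE and MYC T58A against WT (adjusted p = 0.96 and 0.85 with an estimated correlation), and Wnt targets by 0.13 between MYC T58A and MYC OE (0.69). The MYC target differences at 56 h lost camera's preset call without WT at 56 h replicate 1 (0.10 and 0.04) or WT at 0 h replicate 2 (0.03 and 0.04), in MYC OE without 0 h replicate 2 (0.07) and in MYC T58A without 56 h replicate 1 or 2 (0.15 and 0.11) or 0 h replicate 2 or 3 (0.12 and 0.06). The secretory list differed by -0.79 and -0.60 in MYC T58A against WT and MYC OE (adjusted p = 0.65 and 0.69 with an estimated correlation).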

How the results depend on the processing

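The fit without mitochondrial genome genes and the choice of lists followed here came after the data were seen. Of 254 alternative counts of changed genes, 157 lay within 1.5 times the reported count and 97 did not. Of 1440 values for 102 list results past the threshold, 1267 kept direction and side of the threshold. The call was lost in 161, and the sign changed in 12, all of these on leaving out 1 library. With the estimated correlation 94 of the 102 results lost the call and 8 kept it. Of 1449 values for 116 named genes, 1205 kept the call, 244 lost it and 0 changed sign. The cause was not tested except where fewer libraries or another set of genes entered the fit.

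DESeq2 gave 669 (WT, 8 h), 729 (MYC OE, 8 h), 2 (MYC T58A, 8 h), 207 (MYC OE against WT, 0 h), 77 (MYC T58A against MYC OE, 0 h), 47, 2 and 1 for the 8 h responses and 86, 159 and 1 for the 56 h responses (MYC OE against WT, MYC T58A against WT, MYC T58A against MYC OE). With no low-count filter the counts were 315, 322 and 1 at 8 h, 68 and 54 at 0 h, 14 and 1 for the 8 h responses against WT and 26 and 84 for the 56 h responses against WT. A fit of the compared lines alone gave 312 (WT, 8 h), 61 (MYC OE, 8 h), 0 and 0 at 0 h for the same pairs, and 0 and 62 for the 56 h responses against WT. With the host marker score the counts were 1584 (MYC T58A, 56 h), 769 (MYC T58A against WT, 0 h), 0 (MYC T58A against MYC OE, 0 h), and 0 and 3 for the 56 h responses against WT. RLE size factors gave 10 and the fit without mitochondrial genome genes 54 for the 56 h response of MYC T58A against WT.

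The replicate numbers did not pair the samples. Of 87 pairs with the same number 16 had a correlation over 0.1, and 8 of 24 libraries correlated best with their own number. With the replicate block the counts were 1 for MYC OE against WT at 0 h and 5 for the 56 h response of MYC T58A against WT, and the other counts stayed within 1.5 times.

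Leaving out 1 library gave 0 to 7 and 1996 to 2285 genes in WT at 8 h and 56 h, 873 to 1733 between them, 0 to 684 and 2734 to 3857 in MYC OE, 897 to 1632 between them, 0 to 0 and 1523 to 3299 in MYC T58A, and 967 to 2233 between them. At 0 h the ranges were 0 to 482 (MYC OE against WT), 11 to 1166 (MYC T58A against WT) and 0 to 2 (MYC T58A against MYC OE). The response ranges were 0 to 1, 0 to 0 and 0 to 0 at 8 h and 0 to 97, 0 to 125 and 0 to 1 at 56 h.

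With an estimated correlation 94 list results were no longer past camera's threshold. Among them were the MYC targets at 0 h (0.51 and 0.66 against WT in MYC OE and MYC T58A) and the G2/M difference of MYC T58A (1.67). Their adjusted p with an estimated correlation was 0.25, 0.14 and 0.12. Some medians of lists not past the threshold turned, such as that of Wnt targets in MYC T58A at 8 h, from -0.03 to 0.09 without 0 h replicate 1. So did that of G2/M in MYC T58A against WT at 0 h, from 0.04 to -0.33 without WT at 0 h replicate 1. Among list results past the threshold, the medians that changed sign had these ranges without 1 library. In WT at 8 h the G2/M list ran from -0.26 to 0.70 (WT at 0 h replicate 1 turned it). In MYC T58A at 8 h MYC targets ran from -0.14 to 0.03 (0 h replicate 1, 8 h replicate 2) and glycolysis from -0.26 to 0.51 (8 h replicate 3). In MYC OE against WT at 0 h G2/M ran from -0.20 to 0.74 (WT at 0 h replicate 1). In MYC T58A against MYC OE at 0 h Wnt targets ran from -0.25 to 0.05 (MYC OE replicate 3), G2/M from -0.31 to 0.04 (replicate 3 of either line), mitochondrial ribosomal proteins from -0.03 to 0.16 (MYC T58A replicate 1, MYC OE replicate 2) and nucleotide synthesis from -0.01 to 0.21 (MYC OE replicate 2). The glycolysis difference at 8 h of MYC T58A against WT ran from -0.03 to 0.73 (MYC T58A at 8 h replicate 3). Depth limits the lowest genes, such as APCDD1.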

Other observations

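The counts of regrouped libraries in this part were tests chosen after the results were seen. Genes of cholesterol synthesis had medians of 0.80, 0.79 and 0.66 at 56 h in WT, MYC OE and MYC T58A. Of 24 members 18, 18 and 13 rose (19, 20 and 18 rose and 0, 0 and 1 fell adjusted over the list alone), with adjusted p = 0.28, 0.24 and 0.39 with an estimated correlation. Without WT at 0 h replicate 1, 5 rose in WT, and without MYC T58A at 0 h replicate 3, 8 rose in MYC T58A. MSMO1, a sterol oxidase, rose by 1.46 ± 0.27, 1.40 ± 0.22 and 1.38 ± 0.22. Of 23 genes of the unfolded protein response 11, 12 and 4 rose (12, 14 and 5 adjusted over the list alone), with medians of 0.45, 0.32 and 0.20 and adjusted p = 0.21, 0.21 and 0.46 with an estimated correlation. Their number was 4 in WT without 0 h replicate 1 and 2 in MYC T58A without 56 h replicate 1. SEC61B, a subunit of the translocon, rose by 0.89 ± 0.17 in WT and 0.49 ± 0.14 in MYC T58A, and DNAJB9, a chaperone, by 0.87 ± 0.18 in MYC OE. Of 20 TGF-beta and BMP response genes 9, 9 and 7 fell and 1, 2 and 0 rose (9, 10 and 10 fell and 2, 2 and 1 rose adjusted over the list alone), with medians of -0.56, -0.59 and -0.35 and adjusted p = 0.21, 0.17 and 0.23 with an estimated correlation, and 4 fell in WT without 56 h replicate 2. The ligand genes BMP7 and BMP4 fell by 2.02 ± 0.29 and 1.35 ± 0.22 in WT, by 1.43 ± 0.23 and 1.13 ± 0.18 in MYC OE and by 1.48 ± 0.23 and 0.94 ± 0.18 in MYC T58A.

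At 8 h in the line labelled MYC OE, glycolysis and hypoxia genes had a median of 0.98, with 1 of 37 higher over all genes (23 adjusted over the list alone) and adjusted p = 0.24 with an estimated correlation. HK2, a hexokinase, rose by 1.23 ± 0.29 (edgeR adjusted p = 0.045). Among 19 CDK inhibitors and genes of cell-cycle exit 3 rose (5 adjusted over the list alone), namely the MYC antagonist MXD1 (1.10 ± 0.21), CDKN1A (1.25 ± 0.29) and CDKN2B (0.91 ± 0.21), with a list median of 0.31 and adjusted p = 0.057 with an estimated correlation. The junction gene CLDN4 rose by 0.57 ± 0.12, the 1 of 31 junction genes that passed (11 adjusted over the list alone; median 0.26, adjusted p = 0.12 with an estimated correlation). In WT at 8 h ASNS, asparagine synthetase, rose by 1.08 ± 0.23 (edgeR adjusted p = 0.042), the 1 of 28 ATF4 and amino acid supply genes that passed (13 adjusted over the list alone; median 0.45, adjusted p = 0.51 with an estimated correlation). As given for the 8 h comparisons, counts there were 0 without WT at 8 h replicate 1 or 2 or WT at 0 h replicate 1, and 0 without MYC OE at 0 h replicate 1 or 3.

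The share of counts from the mitochondrial genome averaged 5.89, 12.79 and 6.06% in WT at 0, 8 and 56 h, 9.29, 8.09 and 6.55% in MYC OE and 9.66, 10.26 and 6.55% in MYC T58A. Host leukocyte markers had a median of -0.60 in MYC T58A against WT at 0 h, with 2 of 8 lower and adjusted p = 0.14 with an estimated correlation.

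Other splits of the same libraries were counted for groups of 3, and 3 against 3 make 10 splits, too few for a share under 0.05. In MYC OE 4214 genes at 56 h stood against at most 1 in another split, as did 1881 between 8 h and 56 h. In MYC T58A the counts of 2584 and 1722 stood against 0, and the 3 genes between MYC T58A and MYC OE at 0 h stood against 0. In each of these 5 comparisons the real split was the 1 with as many genes. At 8 h in MYC OE 2 of 10 splits gave at least the 184 genes of the real one, the other being 642, which put MYC OE at 8 h replicates 1 and 3 with 0 h replicate 2. In MYC T58A at 8 h the real split gave 0 genes and the highest other 597, where 8 h replicates 1 and 3 stood with 0 h replicate 2. The split with 642 points to a structure of the MYC OE samples other than time, since AXIN2 was at 26.8 to 31.2 CPM in all 3 MYC OE libraries at 0 h and 7.30 to 14.1 CPM at 8 h. The split with 597 also points to a structure of the samples. It exchanges the MYC T58A libraries that went against their times on Wnt targets, and whether that structure is time was not decided. For the difference in response of MYC T58A and MYC OE the real split gave 0 genes at 8 h and at 56 h, and the highest of the others 10 and 11. Where the real count is 0, every split gives at least as many (10 of 10 and 40 of 40), so these counts decide nothing about chance.

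Whether the labels of MYC T58A replicate 2 at 0 h and 8 h were exchanged was asked because of their Wnt targets, which therefore cannot test it, and was tested on other genes. Libraries with the same number were compared, 8 h minus 0 h, although the numbers did not pair the samples. The 235 genes outside that list that passed at 8 h in WT or MYC OE, signed by their direction there, moved by 0.05 in replicate 2, by 0.46 and 0.58 in replicates 1 and 3, and by 0.47 to 0.92 in the lines in which they were chosen. An exchange would put that value below 0 and labels as given would put it above, and 0.05 lies between the bounds of -0.25 and 0.25 set beforehand, so this test did not decide. An exchange, a treated tumour that did not respond and a vehicle tumour with low Wnt activity stay open, and no library was moved to another group. The 0 h library also enters the comparisons of MYC T58A at 0 h and at 56 h, where 3299 genes changed at 56 h without it and 2584 with it. The 8 h library enters the comparison of 56 h with 8 h, where 2233 genes changed without it and 1722 with it.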
